A study of Rattus norvegicus with 12 samples.

How the data were processed

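RNA was measured in 12 samples of rat esophageal tissue on an Affymetrix expression array, 1 array per sample. Per the labels' protocols, rats received subcutaneous injections of 0.2 ml of either N-nitrosomethylbenzylamine (NMBA), a nitrosamine that causes squamous tumors of the rat esophagus, at 0.3 mg per kg body weight, or its solvent of dimethyl sulfoxide and water, 3 times per week for 5 weeks. Rats were kept 3 to a cage. Per the labels' protocols, part of each esophagus was freed of its submucosal and muscle layers, frozen and used for total RNA. The labels give 4 groups of 3 samples: a normal control, and NMBA at week 6, week 15 and week 29, which the labels call the early, middle and late stage of tumor development. The week at which the control rats were sampled is not given in the sources used here, so age and time differ from the controls by an unknown amount. The labels do not tie samples to cages or state that each array is a separate animal, so p-values measure the spread between these samples.

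The deposited table holds log2 probe set signals, 1 column per array, which the authors made with Affymetrix Expression Console, per the submitters' processing notes. The summarization method, its version and any filter are not given in the sources used here. The scale was read from the values, which ran from 2.49 to 14.71. The median log2 signal of the control arrays was 6.42, 6.44 and 6.48, of the week 6 arrays 6.42, 6.44 and 6.42, of the week 15 arrays 6.49, 6.46 and 6.46, and of the week 29 arrays 6.42, 6.42 and 6.42. No scanner files or detection calls were used here, so signal over background was not assessed and the number of arrays limits the precision. No 2 arrays were identical throughout (7 to 47 probe sets had the same value in a pair of arrays), and no array was averaged with another.

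Of 31099 probe sets, 57 array controls were left out and 31042 were tested, with no filter on dim signal. The platform annotation gave 1 gene symbol to 20826 probe sets, several to 436 and did not list 9780. The gene identifiers of 20758 single-symbol probe sets were found in the reference gene table, and 0 symbols changed. Probe sets with several symbols were given no name. For each of 14217 genes, the probe set with the highest mean over the 12 arrays stood for the gene. Probe sets of 1 gene were called in opposite directions for 0, 3 and 8 genes in the comparisons of weeks 6, 15 and 29 with control, for 70 genes between weeks 15 and 6 and for 65 between weeks 29 and 15. No genome coordinates are given, since no build was named.

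Values were used as deposited. Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided), in 1 fit of the 4 groups to all 12 arrays with 8 residual degrees of freedom, and p-values were adjusted by the Benjamini-Hochberg method over 31042 probe sets. A probe set was called at an adjusted p under 0.05. The comparisons were each NMBA week with control, week 15 with week 6, and week 29 with week 15, plus an overall moderated F test and a linear trend over weeks 6, 15 and 29 in the 9 NMBA arrays. Log2 fold changes are given with their standard error (SE) and group values as mean ± SD of 3 arrays. Before the data were examined, 23 gene lists were fixed: proliferation, squamous differentiation, basal keratinocyte, stress keratin and alarmin, prostanoid and cytokine, lymphocyte, myeloid and mast cell, fibroblast and matrix, smooth muscle, skeletal muscle, endothelial, neural, adipocyte, simple and glandular epithelium, oxidative stress and xenobiotic metabolism, p53 and DNA damage, EGFR ligand and AP-1, protease and angiogenesis, interferon response, glycolysis and hypoxia, cholesterol and fatty acid synthesis, circadian clock, and immediate early lists. They were tested with limma's camera at a preset inter-gene correlation of 0.01, with adjustment over the lists of a comparison. Camera with an estimated correlation and fry were run beside it. A list score is the mean log2 signal of its genes in 1 array.

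Genes were named by a rule fixed before the data were examined. It took the 10 largest rises and the 10 largest falls in each comparison with control, and 5 of each in the others, among genes called with non-overlapping groups. Provisional names were skipped. It also took up to 4 called members of each called list (or 2 as values only), the 5 lowest p-values where fewer than 3 genes passed, and always Mki67, Ptgs2, Krt13, Krt14 and Cdkn1a. Other genes are named as chosen after their values were seen.

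The fit was tested on simulated data before use. For week 6 versus control, with 31042 probe sets, it recovered 42% of 50 probe sets changed 1.5-fold, 82% of 50 changed 2-fold, 96% of 50 changed 3-fold and 100% of 50 changed 4-fold, and 9 of 169 calls were false. For the trend, it recovered 98% of 200 probe sets that changed by 2 on the log2 scale between weeks 6 and 29. The simulated noise was independent between probe sets, with the same SD in every group. In the real data genes were correlated (estimated at 0.745 in the proliferation list). Spread also differed between groups, with a muscle score SD of 0.09 at week 6 and 0.76 at week 15. The simulated rates of recovery and of false calls may therefore not hold for the real data.

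Alternatives fixed before the data were examined were quantile normalization, subtraction of the array median, a filter on dim probe sets, an intensity-dependent prior, array weights, the replicate number as a block, a fit of only the arrays compared, each array left out in turn, a 2-fold minimum, the stage order in place of weeks, a week 29 versus week 6 contrast, and for lists the mean of all probe sets of a gene. A pseudocount was not needed on log2 values. Alternatives chosen after seeing the data were the skeletal muscle score as a covariate, the array control GAPDH 3' minus 5' signal as a covariate, and a fit without the 3 week 15 arrays.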

Results

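Gene expression was profiled in esophageal tissue of control rats and of rats sampled at week 6, week 15 or week 29 of NMBA carcinogenesis, with 3 arrays in each group. Genes of striated muscle were among the brightest on every array, although the protocol removed the muscle layers. The signal of Acta1, skeletal muscle actin, lay between 14.03 and 14.71. The skeletal muscle score was 11.77 ± 0.24 (SD, n = 3) in controls, 12.33 ± 0.09 at week 6, 10.72 ± 0.76 at week 15 and 12.11 ± 0.12 at week 29. In the week 15 samples it was 10.83, 11.43 and 9.92, below the lowest control at 11.50. The signal difference between the 3' and 5' array control probe sets of GAPDH, a measure of RNA integrity that is larger in degraded RNA, was 0.40 ± 0.16 in controls, 0.11 ± 0.04 at week 6, 0.40 ± 0.19 at week 15 and 0.17 ± 0.04 at week 29. Arrays of the same group correlated with a mean r of 0.987 to 0.994 across probe sets. Week 6 and week 29 arrays correlated at 0.992 and week 15 and week 29 arrays at 0.958. Probe sets are not independent replicates, so these r values describe the arrays only. The first principal component held 63.9% of the variance, and on it the week 15 arrays (-58.1, -38.9 and -83.4) and the week 29 arrays (20.5, 46.2 and 51.4) lay on opposite sides of the controls. The week 6 arrays (29.64, 34.96 and 37.05) lay on the side of the week 29 arrays. The skeletal muscle score split the arrays in the same way, below every control at week 15 and above every control at weeks 6 and 29. Stage and muscle were therefore not told apart on this component.

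**Figure D1:**
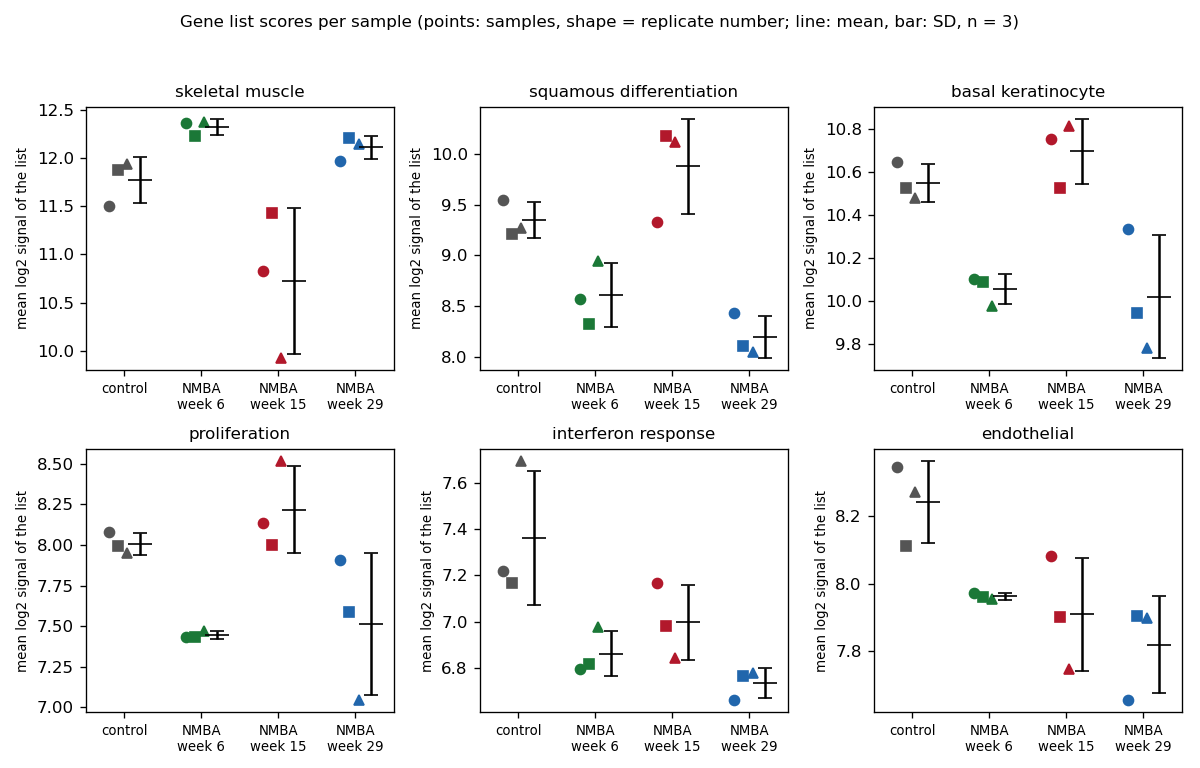
Mean log2 signal of 6 gene lists in each sample, by group, with the group mean and SD (n = 3). The skeletal muscle score of the 3 week 15 samples (9.92 to 11.43) lies below that of every other sample, and the interferon response scores of the NMBA samples lie below the control mean.

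The first question was how the esophagus at week 6, the early stage, differed from that of controls. At week 6, 8 of 37 squamous differentiation, 6 of 21 basal keratinocyte, 12 of 33 interferon-response and 5 of 24 endothelial genes fell and 1 endothelial gene rose (adjusted p = 0.503 with an estimated correlation for each list). Gjb2, the gap junction protein connexin 26, fell by 2.00 ± 0.51 on the log2 scale (SE, n = 3 per group, adjusted p = 0.0378). The keratin gene Krt6c (-1.98, adjusted p = 0.0461), the protease inhibitor gene Serpinb2 (-1.41) and the annexin gene Anxa1 (-1.21) also fell. Mx1, an interferon-induced antiviral GTPase, fell by 1.30 ± 0.32 (adjusted p = 0.033), and Slfn4 fell by 1.69. Acadsb, an acyl-CoA dehydrogenase, showed the largest rise, 1.72 ± 0.31 (adjusted p = 0.0209), followed by Mstn, the muscle growth inhibitor myostatin, at 1.66. Hbb, a beta globin, rose by 1.32, and Mylk3, Phkg1 and Prkab2, which encode kinases or kinase subunits, rose by 1.28, 1.30 and 1.31. With the muscle score as a covariate Mylk3, Phkg1, Prkab2 and Hbb were at 0.67, 0.65, 1.08 and 1.43, and none of them was called.

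Among the fixed lists, 8 squamous differentiation genes of 37 measured fell at week 6 and 0 rose (22 fell when adjusted over the list alone), with a list median of -0.67 and an adjusted p = 0.503 with an estimated correlation. They included Tgm1, the transglutaminase of the cornified envelope (-1.30), and the envelope protein gene Evpl (-0.84). In the basal keratinocyte list 6 of 21 genes fell (14 adjusted over the list alone), including Krt14 (-0.84), Krt5 (-0.71) and the hemidesmosome integrin Itgb4 (-0.75). In the interferon list 12 of 33 genes fell (20 adjusted over the list alone), including Isg15 (-1.10), Rsad2 (-0.99) and Irf7 (-0.73). Endothelial genes fell in 5 of 24 cases and rose in 1 (13 and 1 adjusted over the list alone), with Plvap, a protein of endothelial diaphragms, at -0.71. Only 4 of 45 proliferation genes fell (34 adjusted over the list alone), among them Birc5 (-0.73) and Plk1 (-0.50). For these 4 lists too the adjusted p = 0.503 with an estimated correlation. In the clock list 2 of 20 genes rose (3 adjusted over the list alone), Rora by 0.72 and Tsc22d3 by 0.54. Falls were found in 2 of 18 stress keratin and alarmin genes (3 adjusted over the list alone), 2 of 39 prostanoid and cytokine genes (2 adjusted over the list alone) and 2 of 27 cholesterol and fatty acid genes (5 adjusted over the list alone, with 1 higher). With an estimated correlation the clock and alarmin lists had an adjusted p = 0.324, the prostanoid list 0.503 and the cholesterol list 0.597. None of 39 skeletal muscle genes passed, also when adjusted over the list alone, and the median of that list was 0.46 (adjusted p = 0.64 with an estimated correlation). Beside each of these groups, the skeletal muscle score was higher in each week 6 sample (12.23 to 12.38) than in each control (11.50 to 11.94), and the GAPDH value was 0.11 ± 0.04 against 0.40 ± 0.16.

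At week 6, limma called 2342 probe sets, 1585 higher and 757 lower. Camera called 10 of the 23 lists (fry also called 4 of these 10), with an adjusted p of 7.9e-09 for squamous differentiation and 1.06e-08 for interferon response, and called none with an estimated correlation. The medians of the 13 other lists lay between -0.28 and 0.20. The count fell to 3, 1, 57, 1 and 3 probe sets without control replicate 1, control replicate 3, or week 6 replicate 1, 2 or 3, and to 1377 without week 29 replicate 2. It rose to 4028 without the week 15 arrays, and was 1 with the muscle score as a covariate and 8 with the GAPDH value as a covariate. With the muscle score camera no longer called the skeletal muscle list (median -0.09), by construction, as this list makes the score.

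At week 15, the middle stage, 5 of 18 stress keratin and alarmin genes and 4 of 37 squamous differentiation genes were higher than in controls (adjusted p = 0.105 and 0.363 with an estimated correlation). Lower were 20 of 35 fibroblast, 8 of 39 skeletal muscle, 8 of 19 neural and 7 of 24 endothelial genes (adjusted p = 0.363 with an estimated correlation for each list). S100a9, a calcium-binding alarmin, showed the largest rise, 2.73 ± 0.43 on the log2 scale or 6.63-fold (SE, n = 3 per group, adjusted p = 0.00595), from 4.91 ± 0.16 in controls to 7.64 ± 1.24 at week 15. It was not called in a fit of the 6 arrays alone (adjusted p = 0.0604) or with the muscle score as a covariate (3.33, adjusted p = 0.141). Its partner S100a8 rose by 1.62, the protease inhibitor Slpi by 1.55 and the defensin Defb4 by 1.54. The desmosome genes Dsc1 and Cdsn rose by 1.29 and 1.25. Cyp2a3, a cytochrome P450, rose by 1.28 ± 0.17 (adjusted p = 0.00364), Ereg, an EGFR ligand, by 0.87, and Cyp1a1 by 0.96. Myod1, a master regulator of muscle, showed the largest fall, 1.98 ± 0.27 (log2 fold change -1.98, adjusted p = 0.00354). Ogn, a small matrix proteoglycan, fell by 1.72 ± 0.18 (adjusted p = 0.00221).

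Fibroblast and matrix genes fell in 20 of 35 cases at week 15 (24 adjusted over the list alone), with a median of -0.92 and an adjusted p = 0.363 with an estimated correlation. The collagen genes Col1a2 (-1.42) and Col3a1 (-1.32) were among them. Skeletal muscle genes fell in 8 of 39 cases (32 adjusted over the list alone), with a median of -0.94, and the muscle score of 10.72 ± 0.76 was the lowest of the 4 groups. Neural and Schwann cell genes fell in 8 of 19 cases (8 adjusted over the list alone), led by S100b at -1.52, and smooth muscle genes in 5 of 18 (6 adjusted over the list alone). Endothelial genes fell in 7 of 24 cases (11 adjusted over the list alone), including Clec14a (-0.73) and Sox17 (-0.56). Interferon genes fell in 6 of 33 cases (9 adjusted over the list alone, with 1 higher), including the chemokine gene Cxcl9 (-1.17). These lists also had an adjusted p = 0.363 with an estimated correlation. Control replicate 3 stood apart, with an interferon score of 7.69 (7.22 and 7.17 in the other controls, 7.17, 6.98 and 6.84 at week 15). Its smooth muscle score was 10.73 (10.11 and 10.01 in the other controls, 9.91, 9.88 and 9.75 at week 15). In the glycolysis and hypoxia list 5 of 29 genes fell and 2 rose (12 and 3 adjusted over the list alone, adjusted p = 0.307 with an estimated correlation).

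Stress keratin and alarmin genes rose in 5 of 18 cases at week 15 (6 adjusted over the list alone) and EGFR ligand and AP-1 genes in 2 of 22 (2 adjusted over the list alone), and both lists had an adjusted p = 0.105 with an estimated correlation. Squamous differentiation genes rose in 4 of 37 cases (15 adjusted over the list alone), with a median of 0.60. Oxidative stress and xenobiotic genes rose in 5 of 40 cases (11 adjusted over the list alone, with 3 lower) and cholesterol and fatty acid genes in 4 of 27 with 1 lower (4 and 1 adjusted over the list alone). In the prostanoid and cytokine list 1 of 39 genes rose, Alox12, a lipoxygenase, by 0.70, and 1 fell (0 adjusted over the list alone). These 4 lists had an adjusted p = 0.363 with an estimated correlation. No member of the proliferation list or of the lymphocyte list passed, also when adjusted over the list alone, at medians of 0.21 and 0.16 (adjusted p = 0.641 and 0.378 with an estimated correlation). Beside each of these groups, the muscle scores of the 3 week 15 samples lay below those of every control.

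The week 15 comparison called 2455 probe sets, 528 higher and 1927 lower. Camera called 15 of the 23 lists (fry also called 8 of these 15), with an adjusted p of 7.5e-14 for the fibroblast list, and none with an estimated correlation. The medians of the 8 other lists lay between -0.26 and 0.19. The count was 135 in a fit of the 6 arrays alone, 881 and 927 without control replicate 2 or 3, and 1015 without week 15 replicate 3. With the muscle score as a covariate 0 probe sets were called by limma, with 4286 at an unadjusted p under 0.05. Camera then no longer called the neural (median -0.11), interferon (-0.18), glycolysis (-0.07), smooth muscle (-0.41) and proliferation (-0.14) lists, nor, by construction, the skeletal muscle list (0.06).

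At week 29, the late stage, 22 of 37 squamous differentiation, 17 of 33 interferon-response and 13 of 24 endothelial genes were lower than in controls (adjusted p = 0.442 with an estimated correlation for each list). Stfa3, a stefin protease inhibitor, showed the largest fall, 2.97 ± 0.43 on the log2 scale (SE, n = 3 per group, adjusted p = 0.00596). The small proline-rich envelope genes Sprr3 (-2.68), Sprr1a (-2.62) and Sprr1b (-2.61) fell too, and for Sprr1b the signal was 9.09 ± 0.56 in controls and 6.48 ± 0.18 at week 29. Slc7a11, the cystine transporter, fell by 2.55 ± 0.29 (adjusted p = 0.00232), and Tgm1 fell by 2.09. G0s2, an inhibitor of triglyceride breakdown, showed the largest rise, 1.83 ± 0.39 (adjusted p = 0.0155), followed by Eef1a2, a translation factor of muscle and nerve, at 1.64. Mstn rose by 1.49 and Fbp2, the muscle fructose bisphosphatase, by 1.37.

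Squamous differentiation genes fell in 22 of 37 cases at week 29 (30 adjusted over the list alone), with a median of -1.01, and basal keratinocyte genes in 10 of 21 (15 adjusted over the list alone, with 2 higher), including Krt14 (-1.23) and Itga6 (-0.95). Interferon genes fell in 17 of 33 cases (23 adjusted over the list alone), among them Cxcl10 (-1.35) and Gbp2, a guanylate-binding protein gene (-1.25). Endothelial genes fell in 13 of 24 cases (14 adjusted over the list alone), with Plvap at -1.09 ± 0.11 (adjusted p = 0.00169). Cholesterol and fatty acid genes fell in 11 of 27 cases (13 adjusted over the list alone, with 1 higher), including the sterol synthesis genes Sqle (-1.37) and Cyp51 (-1.03). Stress keratin and alarmin genes fell in 8 of 18 cases (8 adjusted over the list alone). These 6 lists had an adjusted p = 0.442 with an estimated correlation. The myeloid and mast cell list had 6 of 36 genes lower (6 adjusted over the list alone), with an adjusted p = 0.587 with an estimated correlation. The largest falls in it were of RT1-Da (-1.94), RT1-Db1 (-1.82), Cd74 (-1.60) and RT1-Bb (-1.57), which encode MHC class II chains and their chaperone. With the GAPDH value as a covariate RT1-Da was at -1.66 and was not called (adjusted p = 0.068).

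Prostanoid and cytokine genes fell in 8 of 39 cases at week 29 (8 adjusted over the list alone, adjusted p = 0.472 with an estimated correlation) and proliferation genes in 8 of 45 (10 adjusted over the list alone, adjusted p = 0.482 with an estimated correlation). The proliferation fall was uneven, with scores of 7.90, 7.59 and 7.04 in week 29 replicates 1, 2 and 3, against 7.95 to 8.08 in controls. Fibroblast genes fell in 7 of 35 cases (7 adjusted over the list alone), led by Tnc, the matrix protein tenascin C, at -1.72, with an adjusted p = 0.587 with an estimated correlation. Immediate early genes fell in 7 of 27 cases with 1 higher (9 and 1 adjusted over the list alone, adjusted p = 0.479 with an estimated correlation). Neural genes rose in 4 of 19 cases (6 adjusted over the list alone, adjusted p = 0.482 with an estimated correlation). The neural score of week 29 replicate 1, 6.15, lay within the control range of 6.04 to 6.28, and replicates 2 and 3 had 6.55 and 6.65. Adipocyte genes rose in 2 of 15 cases (5 adjusted over the list alone) and clock genes in 2 of 20 (1 adjusted over the list alone), both with an adjusted p = 0.442 with an estimated correlation. None of 39 skeletal muscle genes passed, also when adjusted over the list alone, with a list median of 0.41 and an adjusted p = 0.587 with an estimated correlation. Beside each of these groups, the muscle score lay above that of every control (11.98 to 12.21 against 11.50 to 11.94), and the GAPDH value was 0.17 ± 0.04 against 0.40 ± 0.16.

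Week 29 gave 4705 called probe sets, 2397 higher and 2308 lower (50.9% higher), a balance that depended on processing, with 60.6% higher when the array median was subtracted, 41.5% at a 2-fold minimum and 9.85% with the GAPDH value as a covariate. Camera called 15 of the 23 lists (fry also called 10 of these 15), with an adjusted p of 1.0e-12 for squamous differentiation, and none with an estimated correlation. The medians of the 8 other lists lay between -0.30 and 0.05. With the muscle score as a covariate 2744 probe sets were called, 2630 of them shared with the fit without it. Camera then no longer called the clock list (median 0.16) nor, by construction, the skeletal muscle list (0.06). With the GAPDH value as a covariate 132 were called. The count was 689, 976, 769 and 274 without control replicate 1, control replicate 3, week 29 replicate 2 or week 29 replicate 3, with 38.3%, 34.9%, 34.2% and 27.4% higher.

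**Figure D2:**
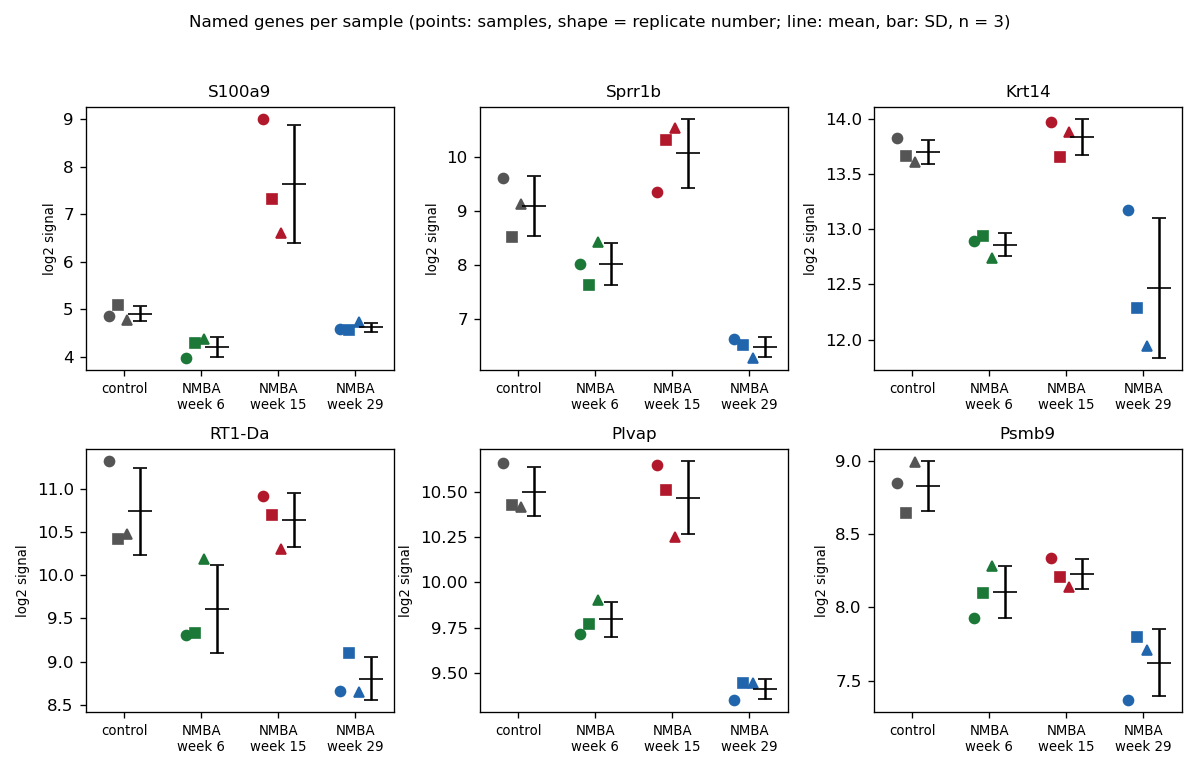
Log2 signal of 6 genes in each sample, by group, with the group mean and SD (n = 3). S100a9 is highest in the 3 week 15 samples (6.59 to 9.01), while Sprr1b, RT1-Da, Plvap and Psmb9 have their lowest group means at week 29.

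Differences between NMBA weeks compare NMBA groups with each other, in a fit of all 12 arrays whose variance includes the controls. Between weeks 6 and 15, S100a9 rose by 3.43 ± 0.43 on the log2 scale (SE, n = 3 per group, adjusted p = 0.000141), and Gjb2, Stfa3, Sprr3 and Sprr2d rose by 2.41, 2.30, 2.21 and 2.18. The slow muscle troponin genes Tnnt1 (-3.77) and Tnnc1 (-3.72) and the muscle genes Trim63 (-2.86), Myoz2 (-2.76) and Myf6 (-2.74) fell. Squamous differentiation genes rose in 32 of 37 cases (33 adjusted over the list alone, adjusted p = 0.423 with an estimated correlation). Proliferation genes rose in 41 of 45 (42 adjusted over the list alone), including Mki67, a proliferation marker, by 1.05 ± 0.28 (adjusted p = 0.011) and Top2a by 1.01. Mki67 was at 0.04 and Top2a at 0.12 with the muscle score as a covariate, no member of the list was called and its median was 0.15, at which camera still called the list (adjusted p = 0.0393). Skeletal muscle genes fell in 37 of 39 cases (37 adjusted over the list alone), with a median of -1.50, and the proliferation and skeletal muscle lists had an adjusted p = 0.45 with an estimated correlation. Clock genes fell in 11 of 20 cases (12 adjusted over the list alone, adjusted p = 0.242 with an estimated correlation), and with the muscle score as a covariate none was called, the median was -0.15 and camera did not call the list (adjusted p = 0.186). From week 15 to week 29, Stfa3 (-3.90), Sprr3 (-3.61), Sprr1b (-3.60), Serpinb12 (-3.27) and Ocm (-3.21) fell, while Ank1, Arpp21, Capn3, Ppp1r3a and Trim63 rose by 2.77, 2.74, 2.71, 2.69 and 2.68. With the muscle score as a covariate these rises were 0.973, 0.87, 0.846, 0.835 and 0.899, and none was called. The falls were then -4.2, -4.06, -3.14, -3.26 and -3.02, with Stfa3, Sprr3 and Sprr1b still called. Squamous differentiation genes fell in 32 of 37 cases (32 adjusted over the list alone) and cholesterol genes in 17 of 27 with 1 higher (17 and 2 adjusted over the list alone), both with an adjusted p = 0.344 with an estimated correlation. Proliferation genes fell in 36 of 45 cases (41 adjusted over the list alone, adjusted p = 0.469 with an estimated correlation), and with the muscle score as a covariate none was called and the median was -0.14, at which camera still called the list (adjusted p = 0.0142). Skeletal muscle genes rose in 32 of 39 cases (32 adjusted over the list alone, adjusted p = 0.44 with an estimated correlation). The muscle score differed by -1.60 between weeks 15 and 6 and by 1.39 between weeks 29 and 15, and the GAPDH value was 0.11 ± 0.04 at week 6, 0.40 ± 0.19 at week 15 and 0.17 ± 0.04 at week 29, beside all of these groups.

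Limma called 11723 probe sets between weeks 15 and 6, 6314 higher and 5409 lower, and 10987 between weeks 29 and 15, 5303 higher and 5684 lower. The larger share changed direction with the array median subtracted (46.5% and 56% higher) and at a 2-fold minimum (27.6% and 61%). Camera called 15 and 14 lists, none of them with an estimated correlation (adjusted p = 0.15 to 0.554 for the 15 and 0.122 to 0.718 for the 14). Fry also called 14 of the 15 and 12 of the 14. With the muscle score as a covariate 8 and 393 probe sets were called. Camera then called the skeletal muscle list in the opposite direction between weeks 15 and 6 (median 0.13, adjusted p = 0.0462) and no longer called it between weeks 29 and 15. As this list makes the score, its change is removed by construction and neither outcome is informative. Camera also no longer called the basal, clock, glycolysis, neural, oxidative stress and smooth muscle lists between weeks 15 and 6 and the clock and fibroblast lists between weeks 29 and 15. The GAPDH covariate gave 4849 and 6915 probe sets.

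**Figure D3:**
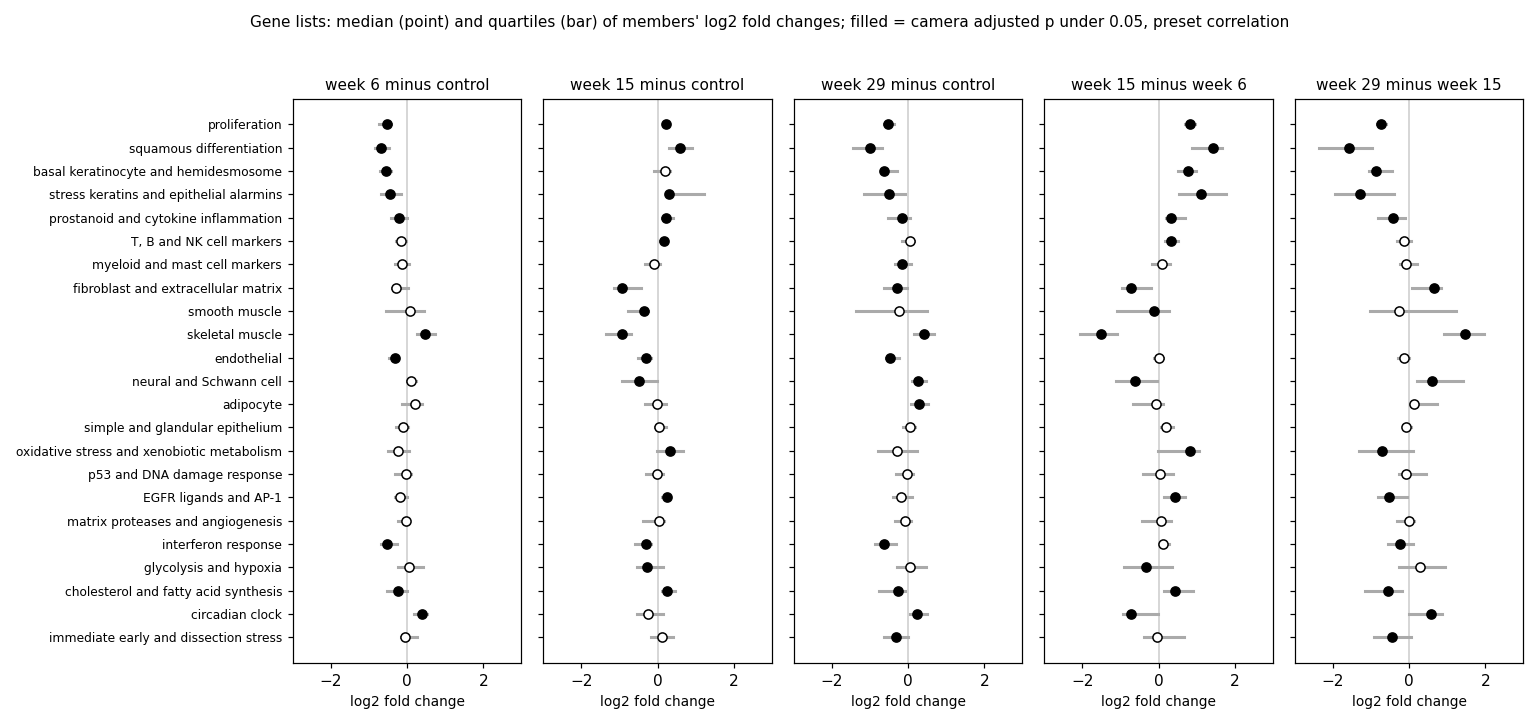
Median log2 fold change of 23 gene lists (points) with the quartiles of their members (bars) in 5 comparisons. Filled points mark lists called by camera at the preset correlation. The skeletal muscle median is -1.50 between weeks 15 and 6 and 1.46 between weeks 29 and 15, and the squamous differentiation median is 1.42 and -1.57.

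A linear change over the NMBA weeks was not found. The distance of week 15 from the other weeks enters the residual of this fit, so its power may be lower than in the simulation. Limma called 0 probe sets for the trend, with 1340 at an unadjusted p under 0.05, where chance gives 1552. The lowest p-values belonged to Klf6, Sult1e1, Lrp3, Rlbp1 and Foxe1, with slopes of -0.026, 0.022, 0.018, 0.020 and 0.043 per week on the log2 scale (adjusted p = 0.997). A contrast of week 29 with week 6 also called 0, with 3005 at an unadjusted p under 0.05 and a lowest adjusted p of 0.172. The overall test called 10900 probe sets as different among the 4 groups. Of the genes fixed in advance, Ptgs2, the inducible cyclooxygenase, had a signal of 3.07 ± 0.05 in controls and 2.92 to 3.17 in the NMBA groups and passed in no comparison. These means lie among the lowest 5% of signals, whose upper limit was 3.36 to 3.49 on the arrays. So near the floor, a change may not be measurable. Mki67 had log2 fold changes of -0.92, 0.13 and -0.73 from control at weeks 6, 15 and 29 and passed in none of these 3. Krt13, a keratin of the upper esophageal layers, fell by 0.77 at week 29. Cdkn1a, the cell cycle inhibitor p21, rose between weeks 15 and 29 by 0.97. The simple epithelium, p53 and DNA damage, and protease and angiogenesis lists were called by camera in no comparison in the fit without a covariate, although fry called the p53 list lower at week 29 versus control (adjusted p = 0.0319), where 5 of its members fell and 2 rose. Medians against control were from -0.11 to 0.05 for the first, near -0.03 for the second and from -0.09 to 0.03 for the last. For the first at weeks 15 and 29 and the last at week 15, the mean, the median and the test differed in sign. Camera called the simple epithelium list, with the muscle score as a covariate, in 4 of the 5 comparisons, with medians of -0.15 at week 6 and 0.25 at week 15 against control, 0.36 between weeks 15 and 6 and -0.19 between weeks 29 and 15. No member passed in these 4, and without the covariate the adjusted p = 0.641 to 0.851 with an estimated correlation.

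The 3 comparisons with control share the same control arrays. Weeks 6 and 29 shared 1168 probe sets called higher and 605 called lower, and 0 were called in opposite directions. Independent lists of these sizes would share 122 and 56.3. The mean of 0 in 50 simulations of unchanged groups against shared controls is no reference, since unchanged groups give almost no calls. Weeks 6 and 15 shared 3 higher and 37 lower, fewer than the 27 and 47 of independent lists, with 523 called in opposite directions (111 for independent lists). Weeks 15 and 29 shared 22 higher and 100 lower, fewer than the 40.8 and 143 of independent lists, with 757 in opposite directions (188 for independent lists). The covariance of log2 fold changes across probe sets was 0.0955 for weeks 6 and 29, -0.0472 for weeks 6 and 15 and -0.045 for weeks 15 and 29, where unchanged groups gave 0.0134. The 3 controls are too few to be split, so part of any excess may come from the shared controls. The muscle score lay above every control at weeks 6 and 29 and below every control at week 15. The mean GAPDH value was 0.11, 0.40 and 0.17 at weeks 6, 15 and 29, against 0.40 in controls. With the muscle score as a covariate 1 of 2342, 0 of 2455 and 2630 of 4705 calls stayed, and with the GAPDH value 1, 2317 and 123. The overlaps were not tested apart from muscle or RNA quality.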

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

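The split counts were planned before the results were seen, except that of the trend. The test of RNA degradation for weeks 15 and 6, those of muscle as the whole cause and of RNA degradation for the MHC class II genes, and that of epithelium for S100a8 and S100a9 were chosen only after the results were seen. So were the limits on tests with a raised standard error, with genes near the floor, with calls that ended, with a count fixed at 0 and with few orders of the muscle score, all of which made verdicts weaker.

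The changes from control differed between time points, by a test of the difference itself, at 11723 probe sets for weeks 6 and 15 and at 10987 for weeks 15 and 29. Camera called 15 lists between weeks 15 and 6. The medians given here are of the 6 lists that it also called against control at both weeks, in opposite directions. They were 0.825 for proliferation, 1.42 for squamous differentiation and 1.12 for stress keratins and alarmins. They were 0.332 for prostanoids and cytokines, -1.5 for skeletal muscle and 0.438 for cholesterol and fatty acid synthesis. Camera called 14 lists between weeks 29 and 15. Picked by the same rule, the medians were -0.732, -1.57, -1.28, -0.429, 1.46 and -0.568 for the same 6 lists, and 0.598 for the neural list. None of these lists was called with an estimated correlation, where the adjusted p = 0.15 to 0.45 between weeks 15 and 6 and 0.122 to 0.469 between weeks 29 and 15. Groups of 3 samples were not tested for outliers.

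Of the 10 splits of the 6 arrays in each comparison of 2 groups, only 1, the real one, gave as many calls, and 10 splits are too few for a share under 0.05. The real values were 2342, 2455, 4705, 11723 and 10987 in the order of the report, and the highest other values were 0, 0, 0, 0 and 1. For the difference among the 4 groups, 1 of 100 partitions, the real one with 10900 calls, gave as many, and the highest other gave 6272. This argues against chance only if the arrays are independent units. The labels do not state that, and a cage or dissection shared within a group could give the same count. For the trend the real count was 0, which all 100 orders reach by construction, so this count says nothing about chance. One of the orders called 9887 probe sets, which points to a structure of the samples other than a linear course.

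The first pattern weighed is the distance of week 15 from weeks 6 and 29. RNA degradation as the whole cause is argued against by the skeletal muscle median of -0.941 between week 15 and control, whose GAPDH values differed by 0.00243. The signal of striated muscle genes was lower at week 15, where 37 of 39 fell against week 6 (median -1.5). How far a lower share of muscle accounts for the other changes stays open. Outside the muscle list, changes predicted from the slope on the muscle score within control and week 29 arrays correlated at 0.544 across probe sets (68.5% with the same sign). However, 6 of 36 orders of the score within these groups gave as large a value. Slopes within groups over all 12 arrays gave 0.775 (76.0% with the same sign). They include the arrays compared, and orders of the score were not run for them. With the score as a covariate 8 of 11723 calls (0.0682%) stayed, while the median size fell from 0.599 to 0.406 and the median SE rose from 0.132 to 0.239, so the calls ended partly because score and group overlap. The stage, age and time since the injections, which the design names, may also account for it and were not tested apart from muscle.

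The next pattern is the lower level of MHC class II genes at week 29, where 6 of 8 measured genes fell with a median of -1.23. RT1-Ba (0.17) and Ciita (0.03) did not pass. Muscle as the whole cause of the change from control is argued against, since with the muscle score as a covariate the median was -1.28 and 6 of 8 were still called. Between weeks 29 and 15 the median with this covariate was -1.33, but 0 of 8 were called. The ratio of the week 6 to the week 29 median, 0.579, leaves a part played by muscle undecided. A loss of all macrophages and dendritic cells is argued against, since the median of 17 other myeloid genes was 0.146 of the MHC class II median, but a loss confined to a subset may remain, as Irf8 (-1.77) and Itgax (-1.26), genes of dendritic cells chosen after their values were seen, fell. RNA degradation stays open for the change from control, since with the GAPDH value as a covariate the median was -1.03 but 0 of 8 were called, as the median SE rose from 0.247 to 0.304, while as the whole cause of the difference from week 15 it is argued against by a median of -0.988 (SE 0.305) with 5 of 8 still called. Changes in antigen presentation are a hypothesis that these tests leave open beside the RNA quality, and it was not tested directly. The fall is not shown to be specific to the late stage. At week 6 the MHC class II median against control was already -0.712, with 1 of 8 genes called lower. The contrast of week 29 with week 6 called 0 probe sets, with a lowest adjusted p of 0.172.

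The last pattern is the rise of S100a8 and S100a9 at week 15, to 6.20 and 9.01, 5.60 and 7.31, and 4.35 and 6.59 in the 3 samples, from control means of 3.76 and 4.91. A larger share of epithelium stays open: the mean rise was 2.17 and the largest rise in the squamous differentiation list 1.29, the sample with the most S100a9 had a squamous score of 9.33, within the control range of 9.21 to 9.55, and the one with the lowest muscle score, 9.92, had the least, all of which go against it, but these are single samples and a pair picked for its size that starts near the floor of the array. Neutrophils stay open too: the median of 10 other neutrophil genes was 0.175, but these genes had a mean control signal of 4.77, near the floor of the array. With the muscle score as a covariate S100a9 was at 3.33 and not called (adjusted p = 0.141). An alarmin response of the epithelium in the middle stage may be another explanation, and it was not tested.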

How the results depend on the processing

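The muscle score covariate, the GAPDH covariate and the fit without the week 15 arrays were chosen after the data were seen, and the other alternatives before. The cause of a change was not tested unless stated. A pseudocount was not run, as values were log2. Signal over background was not assessed.

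For week 6 versus control (2342 called) array weights gave 6909, the 6 arrays alone 4391, the muscle covariate 1, the GAPDH covariate 8, the fit without week 15 arrays 4028 and a 2-fold minimum, by its construction, 207. For week 15 (2455) the 6 arrays gave 135, the muscle covariate 0 with 4286 at an unadjusted p under 0.05, and the 2-fold minimum 527. For week 29 (4705) weights gave 9409, the muscle covariate 2744, the GAPDH covariate 132 and the 2-fold minimum 468. The muscle covariate, the GAPDH covariate and the 2-fold minimum gave 8, 4849 and 2203 between weeks 15 and 6, 393, 6915 and 2521 between weeks 29 and 15, and 160, 4452 and 1111 for any difference, which was 5006 without week 15. The trend stayed at 0 under each alternative run. Quantile normalization, median subtraction, the filter on dim probe sets and the intensity-dependent prior left each count within 1.5 times. The share called higher crossed 50% under some alternatives. Between weeks 15 and 6 it was 53.9%, with 46.5% after median subtraction, 47.8% without dim probe sets, 31.4% with the GAPDH covariate and 27.6% at a 2-fold minimum. Between weeks 29 and 15 it was 48.3%, with 56% after median subtraction, 58.2% with the GAPDH covariate, 79.9% with the muscle covariate and 61% at a 2-fold minimum. At week 29 it was 50.9%, with 60.6% after median subtraction, 47.6% without dim probe sets, 41.5% at a 2-fold minimum, 9.85% with the GAPDH covariate, and 38.3%, 34.9%, 34.2% and 27.4% without control replicate 1 or 3 or week 29 replicate 2 or 3. Leaving out each array gave 48.5% to 55.9% between weeks 15 and 6 and 44.7% to 53.3% between weeks 29 and 15.

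Leaving out each array gave 1 to 3454 calls for week 6, 881 to 3057 for week 15, 274 to 6120 for week 29, 8965 to 11704 between weeks 15 and 6, 8115 to 11490 between weeks 29 and 15, 0 to 0 for the trend and 8861 to 11232 for any difference. The week 6 count fell over 1.5 times without control replicate 1 (3) or 3 (1), week 6 replicate 1 (57), 2 (1) or 3 (3), or week 29 replicate 2 (1377). The week 15 count did so without control replicate 2 (881) or 3 (927) or week 15 replicate 3 (1015), and the week 29 count without control replicate 1 (689) or 3 (976) or week 29 replicate 2 (769) or 3 (274).

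With the muscle covariate some directions turned. Skeletal list medians became -0.0886 (week 6 versus control), 0.0585 (week 15 versus control) and 0.132 (weeks 15 and 6), by construction, as the list makes the score, and camera called the last in the opposite direction (adjusted p = 0.0462). Between weeks 29 and 15 that median was 0.0583, with its sign kept, and only the direction given by camera turned (adjusted p = 0.783). The proliferation median at week 15 became -0.139, Ckmt2 at week 15 0.0532, Pfkm, Slc16a3 and Bhlhe41 between weeks 15 and 6 0.000575, 0.188 and 0.00251, and Mki67 between weeks 29 and 15 0.0205. Of 69 called list results 50 held with this covariate, 64 with quantile normalization, 48 with fry and 0 with an estimated correlation. Fry also called 5 list results that camera did not. The muscle covariate also newly called 12 of 46 other list results, 4 of them of the simple epithelium list. Of 305 called gene results 67 held with the muscle covariate, 172 with the GAPDH covariate, 236 with the 6 arrays alone and 292 with quantile normalization.

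The replicate numbers did not pair the samples: of 18 same-number pairs 8 correlated over 0.1 (range -0.413 to 0.29), and 3 of 12 arrays correlated best with their own number. With the replicate block the counts were 2420, 2432, 4556, 11073, 10521, 0 and 10065, in the order above.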

Other observations

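The gene sets for fiber types and red cells were chosen only after the data were seen.

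The 8 slow fiber genes measured all fell between weeks 6 and 15, with a median of -2.69, and 10 of 11 fast fiber genes fell, with a median of -1.06. Against control the slow set had medians of 1.15, -1.37 and -0.06 at weeks 6, 15 and 29 and the fast set 0.30, -0.72 and 0.38. The difference between the sets was not tested, and the mean control signal was 9.4 for the slow and 12.5 for the fast set, the latter closer to the highest array value of 14.71, where changes can be compressed. The beta globin gene Hbb rose by 1.32 ± 0.18 at week 6, fell by 1.12 ± 0.18 at week 15 and rose by 1.21 ± 0.18 at week 29 against control (adjusted p = 0.015, 0.00767 and 0.00688). The other 4 red cell genes measured did not pass at week 15 (Hba-a3 0.10, Alas2 0.0033, Slc4a1 0.17, Hbe1 0.24), and the median of the 5 was 0.105. Alas2, the heme synthesis enzyme of red cells, rose by 0.63 at week 29. With the muscle score as a covariate, Hbb was among the 8 probe sets still called between weeks 15 and 6, at -2.77 ± 0.36 (adjusted p = 0.0488).

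In the comparisons with control, 36 probe sets were lower at all 3 weeks and 1 was higher. Weeks 6 and 15 alone shared 37 lower probe sets, fewer than the 47 of independent lists. The 36 include 22 named genes, among them the endothelial genes Aqp1, Cd93, Clec14a, Emcn and Sox17 and the interferon-induced genes Cxcl9, Irf1, Gbp4, Gbp7 and Psmb9, singled out after their values were seen. The 3 comparisons share their control arrays, so a gene that was high by chance in the controls would be lower in all 3.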
